A study of Mus musculus with 5 samples.

How the data were processed

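RNA was sequenced from adult mouse cardiomyocytes of 2 groups, Control-CMs (2 libraries) and OSKM-CMs (3 libraries). Per the labels, cells were isolated from hearts of injected mice, total RNA was extracted with Trizol, and libraries were made with standard Illumina protocols. The labels do not say whether each library came from a separate mouse, so the p-values measure only the spread between these samples. The authors' processing notes name CASAVA 1.8.2, FastQC, Trimmomatic, STAR 2.5.3 and HTSeq and the genome build mm9. They state neither the annotation, the strand setting nor how reads shared between genes were assigned, so reads of overlapping antisense genes or of paralogues cannot be ruled out for a single gene.

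The deposited table held 12446 genes, each with an Ensembl identifier, a symbol, a biotype and a value per library. The authors' library values were RPKM, reads divided by gene length and library size, with no prior count added. That unit was inferred from the values, since no header names it, and RPKM cannot be told apart from a fragment-based unit. The authors also deposited a log2 fold change of OSKM-CMs against control and an average log2 abundance over the libraries. Beside these stood the authors' likelihood-ratio score for each gene. The last deposited columns were the authors' p-value and FDR from that test, and the FDR equalled the Benjamini-Hochberg adjustment of the p-value for all 12446 genes. All 12446 listed genes had at least 1 CPM in at least 2 libraries, so genes below that level were not analysed here. The file gave no coordinates, and symbols were taken from it as listed (77 entries shared a symbol with another).

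Because RPKM values within a library are whole multiples of a step per gene, whole read numbers were recovered from them. All 12446 genes (100%) gave whole numbers within 0.0001 reads. For 209 genes a common factor of the reads was settled from the authors' average abundance. The recovered reads summed to the recovered library totals within 2 reads, so these totals cover the listed genes and not the full sequencing depth. They ranged from 2691796 to 3861805. The floor for a gene with 0 reads was set at 3 reads, pooled over a group (0.484 CPM for controls) where a fold is given. Recovery was tested on simulated data, where 5 of 5 library totals and the reads of all 12446 genes, up to a whole multiple, were recovered.

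The test planned before the data were examined was a quasi-likelihood test on counts, with limma on log2 values as the fallback should the files hold normalized values. The files held RPKM, so the fallback was used. RPKM were rescaled with TMM factors (trimmed mean of M values, with 30% of log ratios and 5% of abundances trimmed), computed from the recovered reads. The fallback as planned named no scaling, so TMM was carried over from the count plan after the unit was known. Genes with a mean RPKM of at least 1 were kept, 10915 in all. Log2 of scaled RPKM plus 1 was fitted with limma 3.58.1 (R 4.3.3), with an abundance trend and robust empirical Bayes, 2-sided, and the Benjamini-Hochberg adjustment at 0.05. The added 1 understates log2 fold changes of genes with low values. Folds of mean scaled RPKM are given for some of these genes, and log2 values printed alone remain understated. No paired analysis was possible because the groups share only 1 replicate number. On simulated data with the same group sizes, the test called 24% of genes changed 1.5-fold, 68.1% of those changed 2-fold and 98.0% of those changed 4-fold, with 5 unchanged genes among 144 calls. The simulation drew genes independently with a common dispersion of 0.00377 and changed few genes, all of them well read. These shares therefore need not hold for the real libraries or for genes with few reads.

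Gene lists (34, with 1115 entries, 882 of them in the table) were fixed in advance and tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which left 29. They covered pluripotency, cell cycle, p53, sarcomere, fetal, calcium and ion channel, cardiac transcription factor, metabolic, ribosome biogenesis, chromatin, stress, interferon, cytokine, immediate early, epithelial, mesenchymal, YAP/TEAD and autophagy genes, and markers of other cell types. Camera was repeated with the correlation estimated from the residuals, under which none of the 11 calls held, and fry was run as an alternative. With 3 residual degrees of freedom such estimates are imprecise, and camera with an estimated correlation also bases its p-values on those 3 degrees of freedom. A call lost in that form therefore need not reflect correlation between genes. The ribosome biogenesis list had an estimated correlation of 0.00876, below the preset. Its camera adjusted p was still 0.202 in that form, against 8.98e-10 with the preset. Members are also counted with p adjusted over the list alone. Genes named in the text were chosen by a fixed rule: the 4 factors; 16 landmark genes; the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap; and up to 3 members of each list with the smallest p. Further list members named as examples, or to spell out a small count, were chosen after their values were seen. Counting intervals of read ratios are 95% exact binomial intervals.

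Alternatives tried were median-ratio and upper-quartile scaling, library totals alone, no filter, stricter filters (at least 1 CPM in at least 3 or at least 2 libraries, which test more genes than the RPKM minimum does), limma voom on recovered reads, empirical Bayes without robustness, abundant genes left out of the scaling, leaving out each library in turn, and changes to the list tests. A DESeq2 test was also planned as an alternative for counts and was not run. Pseudocounts of 0.1 and 5 were added after the data were seen. Gene length came from the deposited values and GC content from a mouse reference annotation, in which 12172 identifiers (97.8%) were matched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.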

Results

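Bulk RNA sequencing was compared between cardiomyocytes isolated from adult mouse hearts after delivery of 4 reprogramming factors and cardiomyocytes that received a control vector. The OSKM-CMs group held 3 libraries (replicates 1, 2 and 3) from male C57BL/6 mice given a mixture of adeno-associated virus vectors for Oct4, Sox2, Klf4 and Myc. The Control-CMs group held 2 libraries (replicates 3 and 5) from mice given a vector for blue fluorescent protein (BFP). All vectors used the promoter of cardiac troponin T, which is active in cardiomyocytes. The mice were injected at 8 weeks, and their age is given as 12 to 14 weeks. The deposited table listed 12446 genes, of which 11586 were protein-coding. Reads over the listed genes totalled 2773242, 2780751 and 2691796 in OSKM-CMs replicates 1, 2 and 3, and 3519628 and 3861805 in Control-CMs replicates 3 and 5. A gene with 0 reads could have had up to 3 reads, which is a floor of 0.777 to 1.11 CPM (counts scaled to library size) in a single library. Floors and counting intervals cover counting error only.

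The comparison asked how the transcriptome of adult cardiomyocytes differed when the 4 factors were expressed. Transcripts of all 4 factors were far higher in OSKM-CMs. Pou5f1 (ENSMUSG00000024406.9), the gene of Oct4, had 344, 262 and 266 reads in the 3 OSKM libraries and 0 reads in both controls. Its scaled RPKM (reads per kilobase and library size) was 41.9 ± 6.80 (SD, n = 3) in OSKM-CMs, at least 194-fold higher against a floor of 3 reads pooled over the controls (limma, Benjamini-Hochberg adjusted p = 1.49e-05). Sox2 (ENSMUSG00000074637.3) had 391, 254 and 261 reads against 0 and 0, and a level of 39.8 ± 10.3 that was at least 202-fold higher against the same floor (limma adjusted p = 1.75e-05). Klf4 (ENSMUSG00000003032.7) was also read in controls, at 4.44 ± 1.23 (SD, n = 2), and rose to 29.7 ± 7.84 in OSKM-CMs, 6.69-fold (log2 fold change 2.49, SE 0.23, limma adjusted p = 0.000484). Myc (ENSMUSG00000022346.8) rose 52.9-fold, from 0.536 ± 0.0877 to 28.4 ± 6.84 (log2 fold change 4.23, SE 0.21, limma adjusted p = 3.87e-05). Reads of vector-borne cDNA entered these values only where they matched exons of the genome, so vector and endogenous transcripts were not separated.

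**Figure D1:**
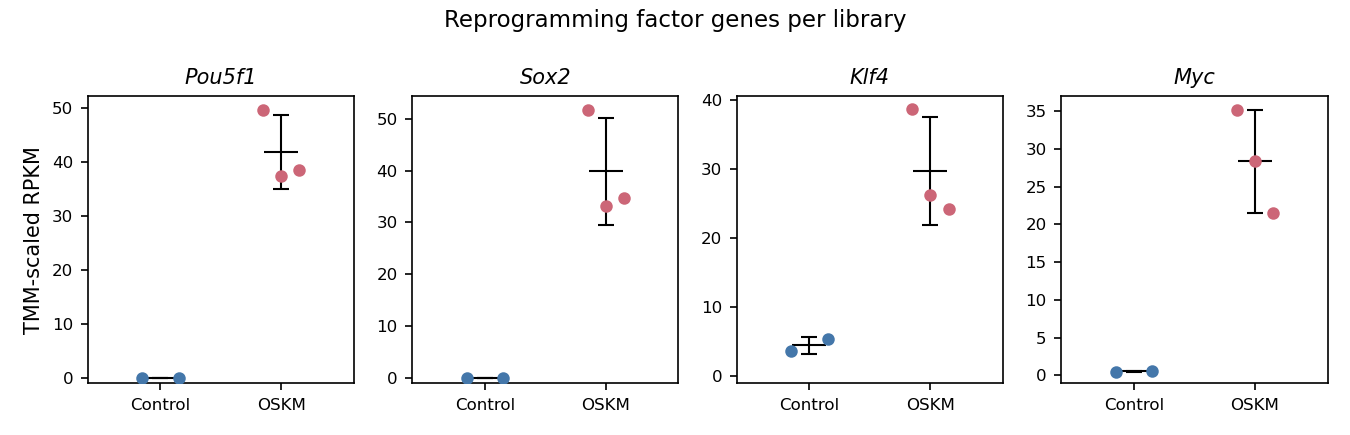
TMM-scaled RPKM of Pou5f1, Sox2, Klf4 and Myc in each library, with points for the libraries of Control-CMs (n = 2) and OSKM-CMs (n = 3) and bars for the group mean ± SD. Pou5f1 and Sox2 lie at 0 in both controls and average 41.9 and 39.8 in OSKM-CMs, and Klf4 averages 4.44 in controls and 29.7 in OSKM-CMs.

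Across the transcriptome, 3298 of 10915 tested genes changed (limma, Benjamini-Hochberg adjusted p below 0.05), 1740 of them higher and 1558 lower in OSKM-CMs, and 1231 changed at least 2-fold. That last count was 528 with 5 in place of 1 added before logs, 1564 with 0.1, and 1785 with limma voom, which also tested more genes. A further 1314 genes had an unadjusted p below 0.05 without passing the correction. The groups did not overlap for 6318 genes, or 57.9%, where chance gives 20% for 2 against 3 libraries. The first principal component took 73.6% of the variance and separated the groups, and the second took 12.5% and separated the 2 controls from each other. Among the genes with the largest rises were 3 sarcomere genes of the embryonic heart or slow skeletal muscle. Tnni1 (ENSMUSG00000026418.10), slow skeletal troponin I, had 2 reads in the controls together and 1877 in OSKM-CMs, a ratio of 627 with a 95% exact counting interval of 173 to 5184. Tnnt1 (ENSMUSG00000064179.6), slow skeletal troponin T, rose 60.7-fold to 529 ± 157 scaled RPKM. Myh7 (ENSMUSG00000053093.9), the beta myosin heavy chain, rose 31.8-fold, from 43.7 ± 10.3 to 1388 ± 559 scaled RPKM. Upp1 (ENSMUSG00000020407.7), uridine phosphorylase, rose 53.6-fold, and Timp1 (ENSMUSG00000001131.5), an inhibitor of matrix metalloproteinases, rose 44.3-fold. Sprr2a3 (ENSMUSG00000074445.1), a small proline-rich protein gene, had no control reads and was at least 62.2-fold higher (limma adjusted p = 0.000694), but it did not pass with limma voom (adjusted p = 0.0751). The largest falls included Ces1d (ENSMUSG00000056973.6), a carboxylesterase, from 100.3 ± 2.70 to 2.14 ± 2.51 scaled RPKM. Scn4b (ENSMUSG00000046480.5), a sodium channel beta subunit, fell from 11.6 ± 0.571 to 0.174 ± 0.198, and Kcnip2 (ENSMUSG00000025221.9), a subunit of the transient outward potassium channel, fell from 52.4 ± 6.15 to 4.88 ± 2.63. Also among the largest falls were Efnb3, Rpl3l, Lrrc4b and Ybx2, with log2 fold changes from -3.22 to -2.84. Lrrc4b had 1 read in OSKM-CMs against 136 in controls, a ratio of controls over OSKM-CMs of 203 with an exact counting interval of 35.9 to 8094. Scaling to library totals alone moved the median of all tested genes from 0.02 to 0.36 on the log2 scale and gave 3985 genes higher and 650 lower. Without OSKM-CMs replicate 3, 1158 genes were higher, and without Control-CMs replicate 5, 953 were lower.

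Genes of the fetal and dedifferentiation program rose as a group. Of 27 tested members, 17 rose, 0 fell and 10 did not pass (17 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 1.15 (camera adjusted p = 7.16e-08). The call was lost at adjusted p = 0.47 with an estimated correlation. Besides Tnni1, Tnnt1 and Myh7, Ncam1 (ENSMUSG00000039542.8), a neural cell adhesion molecule, rose 165-fold, from 0.112 ± 0.0686 to 18.5 ± 0.465 scaled RPKM. Acta1, skeletal alpha-actin, rose 3.59-fold, from 129.05 ± 3.90 to 463 ± 101 scaled RPKM, and smooth muscle actin Acta2 rose with a log2 fold change of 1.90. The natriuretic peptide genes Nppa and Nppb rose 3.51-fold (limma adjusted p = 0.000971) and 2.24-fold (0.00173). Atrial myosin light chain Myl7 rose with a log2 fold change of 2.66 and Ankrd1 with 2.00. Acta2, Ctgf and Vim of this list are also expressed by fibroblasts or mural cells, and in the same libraries fibroblast markers had a median log2 fold change of 0.65 and endothelial markers one of -0.67.

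Adult sarcomere genes were lower on balance but moved both ways. Of 37 tested members, 6 rose, 18 fell and 13 did not pass (7 higher and 19 lower adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 0.00188). This call too was lost, at adjusted p = 0.47 with an estimated correlation. Myh6 (ENSMUSG00000040752.9), the alpha myosin heavy chain of the adult mouse ventricle, fell from 4720 ± 364 to 1945 ± 512 scaled RPKM (log2 fold change -1.31, SE 0.20, limma adjusted p = 0.00338). Tcap, a titin-binding Z-disc protein, fell by 2.05 on the log2 scale, Trim63, a muscle ubiquitin ligase, by 1.64, and Tnni3, cardiac troponin I, by 1.31. Tnnt2 had a log2 fold change of -0.60 (limma adjusted p = 0.0118) that did not pass with library totals alone (-0.18, adjusted p = 0.186). The 6 members that rose were Synpo2l, with a log2 fold change of 2.43, and Myom3, Xirp1, Mybpc3, Flnc and Myoz2, with changes from 0.54 to 0.92. With library totals alone the list had 12 members higher and 10 lower and a median of -0.04, against a median of 0.36 for all genes. Matrix genes, with a median of 1.21, were higher in the same libraries.

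Calcium handling and ion channel genes fell together, with 31 of 51 members lower, 6 higher and 14 not passing (6 higher and 32 lower adjusted over the list alone). Their median log2 fold change was -0.71 (camera adjusted p = 4.75e-08; adjusted p = 0.47 with an estimated correlation). Atp2a2 (ENSMUSG00000029467.8), the calcium pump of the sarcoplasmic reticulum, fell from 3392 ± 125 to 1359 ± 220 scaled RPKM (log2 fold change -1.33, SE 0.15, limma adjusted p = 0.000804). Ryr2, the calcium release channel, fell by 1.53 on the log2 scale, and Pln, phospholamban, by 1.39. The potassium channel genes Kcnj5 and Kcnk3 fell by 2.34 and 2.04. Members that rose included Kcne1 at 1.43, Kcna4, Casq2 at 0.44 and S100a1 at 0.35. The calcium and ion channel list had 21 members lower, 10 higher and a median of -0.38 with library totals alone. Cardiac transcription factor genes were not called by camera, with 3 of 22 higher, 5 lower and 14 not passing (5 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.126), although fry, which tests a list against no change, gave an adjusted p of 0.0361 (lower). Within it Hopx fell by 1.47 and Klf15 by 1.24, whereas Tbx20 rose by 1.03 and Foxo3 by 0.86. In the same libraries the medians of matrix genes and fibroblast markers were 1.21 and 0.65, and that of endothelial markers was -0.67.

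**Figure D2:**
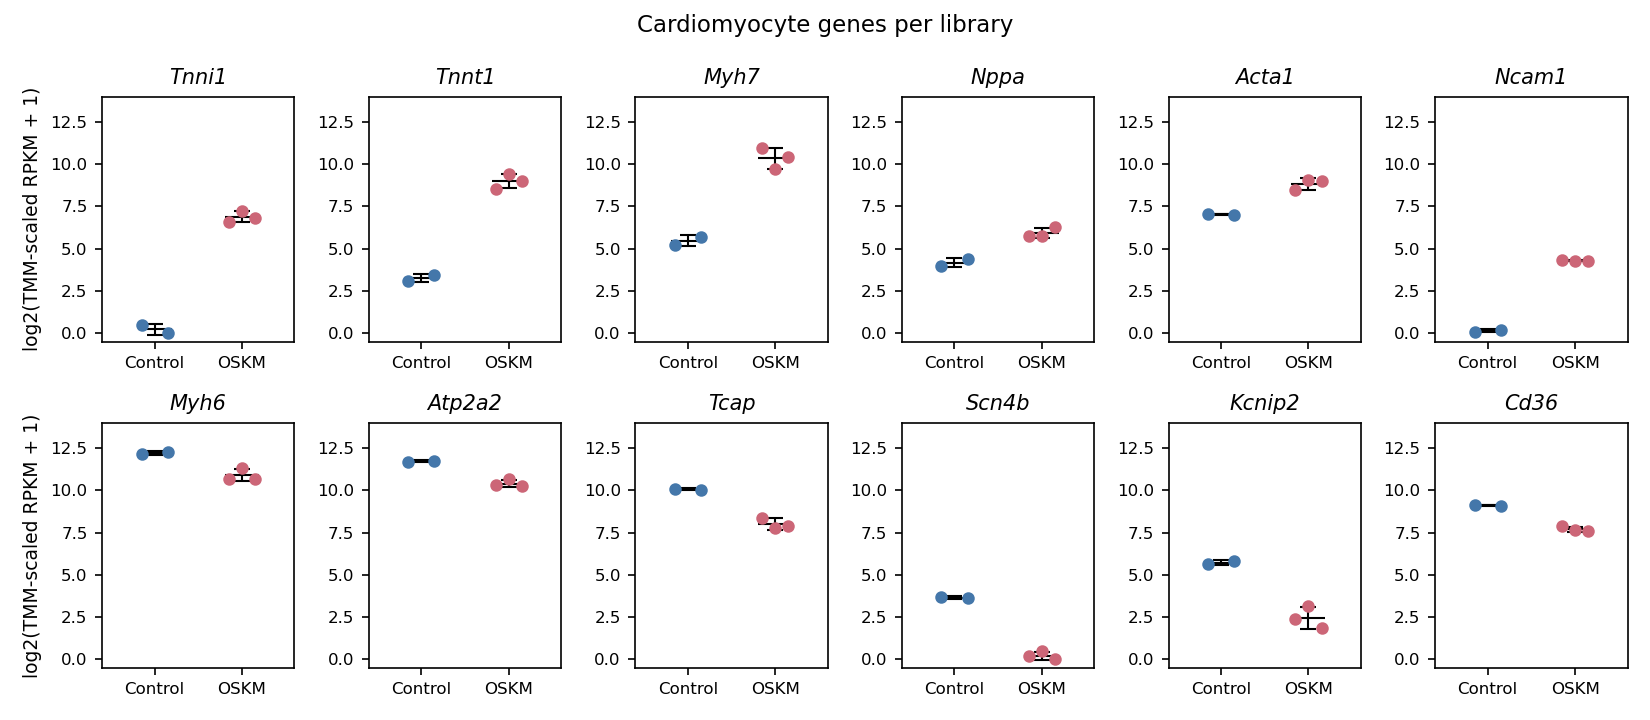
Log2 of TMM-scaled RPKM plus 1 for 12 cardiac and metabolic genes, with points for the libraries of Control-CMs (n = 2) and OSKM-CMs (n = 3) and bars for the mean ± SD. Tnni1, Tnnt1, Myh7, Nppa, Acta1 and Ncam1 are higher in every OSKM library than in both controls, and Myh6, Atp2a2, Tcap, Scn4b, Kcnip2 and Cd36 are lower, with log2 fold changes from 6.66 (Tnni1) to -3.44 (Scn4b).

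Genes of mitochondrial energy metabolism were lower. Of 79 tested nuclear genes of oxidative phosphorylation, 71 fell, 2 rose and 6 did not pass (2 higher and 75 lower adjusted over the list alone), with a median log2 fold change of -0.74 (camera adjusted p = 4.85e-23; adjusted p = 0.47 with an estimated correlation). Ndufv1, a complex I subunit, fell from 423 ± 17.6 to 205 ± 5.88 scaled RPKM. Cox6a2, the heart and skeletal muscle form of a cytochrome oxidase subunit, fell by 1.59 on the log2 scale. The 2 members that rose were Cox6a1 at 1.29 and Cox8a at 1.09, which are the non-muscle forms of their subunits. The citric acid cycle list had 19 of 24 members lower, 0 higher and 5 not passing (1 higher and 20 lower adjusted over the list alone; median -0.62; camera adjusted p = 2.20e-08; adjusted p = 0.47 with an estimated correlation). Idh3b fell by 1.17, the mitochondrial pyruvate carrier gene Brp44 by 1.03 and Ogdh by 0.88. Fatty acid oxidation had 37 of 50 members lower, 1 higher and 12 not passing (1 higher and 39 lower adjusted over the list alone; median -1.02; camera adjusted p = 2.95e-15; adjusted p = 0.47 with an estimated correlation). Decr1 fell by 1.72, the medium-chain dehydrogenase Acadm by 1.34, the fatty acid transporter Cd36 by 1.41 and the nuclear receptor Ppara by 1.41, while Cpt1a, the form of carnitine palmitoyltransferase abundant in liver, rose by 0.72. Cpt1b, its muscle form, had a log2 fold change of -0.51 (limma adjusted p = 0.117). It rested on few reads, 11, 8 and 5 in OSKM-CMs replicates 1, 2 and 3 and 15 and 16 in Control-CMs replicates 3 and 5. Its means were 1.49 scaled RPKM in controls and 0.772 in OSKM-CMs, where the added 1 shrinks the log2 value. The coactivator Ppargc1a had a log2 fold change of -0.52 (limma adjusted p = 0.0688). Ppargc1a passed without OSKM-CMs replicate 2 (-0.63, adjusted p = 0.0494), without Control-CMs replicate 3 (-0.76, adjusted p = 0.0389) and with limma voom (-0.55, adjusted p = 0.0224). With library totals alone, which moved the median of all genes to 0.36, the lower members numbered 37 of 79 for oxidative phosphorylation (3 higher, median -0.33), 7 of 24 for the citric acid cycle (2 higher, median -0.22) and 27 of 50 for fatty acid oxidation (3 higher, median -0.63).

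Glycolytic genes moved both ways, with 10 of 24 higher, 6 lower and 8 not passing (10 higher and 7 lower adjusted over the list alone; median 0.13; camera adjusted p = 0.238; fry adjusted p = 0.0126, higher). Aldoc, an aldolase typical of brain, had no control reads and was at least 93.1-fold higher. Pgam1 rose by 2.32 on the log2 scale, the platelet-type phosphofructokinase Pfkp by 1.99 and the lactate dehydrogenase gene Ldha by 1.25. The muscle phosphofructokinase Pfkm fell by 1.35, Ldhb by 1.43 and the insulin-responsive glucose transporter Slc2a4 by 1.55. The list had 16 members higher and 4 lower and a median of 0.53 with library totals alone. Transcripts encoded by mitochondrial DNA moved with the same groups, taking 11.1%, 10.5% and 9.76% of reads in OSKM-CMs replicates 1, 2 and 3 and 21.2% and 24.7% in Control-CMs replicates 3 and 5. The 10 most abundant genes took 17.3% to 19.3% of reads in OSKM-CMs and 29.4% and 32.6% in controls. Matrix genes (median 1.21) and fibroblast markers (median 0.65) were higher and endothelial markers (median -0.67) lower in the libraries where energy genes fell.

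Mitotic genes rose from low levels. In the list of G2/M and mitosis genes, 18 of 25 tested members rose, 2 fell and 5 did not pass (18 higher and 3 lower adjusted over the list alone), with a median log2 fold change of 1.04 (camera adjusted p = 0.000231; adjusted p = 0.47 with an estimated correlation). Anln, a cytokinesis protein, rose 22.7-fold, from 0.119 ± 0.168 to 2.70 ± 0.293 scaled RPKM, and Top2a rose 13.5-fold to 2.17 ± 0.683. Ccna2, cyclin A2, had 74 reads in OSKM-CMs and 3 in controls, a ratio of 16.5 with an exact counting interval of 5.43 to 81.8. Cdk1 had 50 reads against 3, a ratio of 11.1 with an interval of 3.60 to 55.8 (log2 fold change 1.15, limma adjusted p = 0.0147), and did not pass without Control-CMs replicate 3 (0.99, adjusted p = 0.0736). The proliferation marker Mki67 went from 0.512 ± 0.451 to 2.06 ± 0.655 scaled RPKM (log2 fold change 1.03, limma adjusted p = 0.0253), and did not pass without OSKM-CMs replicate 2 (0.85, adjusted p = 0.0678), without OSKM-CMs replicate 3 (1.03, adjusted p = 0.068) or without Control-CMs replicate 5 (0.73, adjusted p = 0.129). Spc24 and Cenpf were the members that fell, by 1.25 and 0.68. Without OSKM-CMs replicate 2 the list had 17 tested members and its camera adjusted p was 0.0691. Of its 49 members in the table, 25 met the RPKM minimum, which members near 0 in controls could meet only through OSKM-CMs. The count and median therefore cover members selected partly by the change. The camera call also held with no filter, but that setting covers only listed genes, all with at least 1 CPM in at least 2 libraries. Members near 0 in controls could reach that level too only through OSKM-CMs, so the setting cannot remove this selection. Mitotic genes are shared by all dividing cells, and in the same libraries 6 of 22 fibroblast markers were higher (median 0.65; adjusted p = 0.58 with an estimated correlation).

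The G1/S and DNA replication list did not pass, with 6 of 27 higher, 0 lower and 21 not passing (5 higher and 0 lower adjusted over the list alone; median 0.22; camera adjusted p = 0.0867), although it passed in 5 of 19 other settings (no filter, both stricter filters, limma voom and without OSKM-CMs replicate 1), with an adjusted p from 0.0149 to 0.58 over all of them. The 2-library filter kept the same 12446 genes as no filter, limma voom also tested 12446 and the 3-library filter 12387. These passes without the RPKM minimum are therefore not separate evidence. Members of the G1/S list called higher numbered 12 with library totals alone. It contained Ccnd1, cyclin D1, which rose 2.76-fold, from 4.89 ± 0.325 to 13.5 ± 2.04 scaled RPKM (limma adjusted p = 0.00139), and Ccnd2, which rose 1.79-fold. Cell cycle inhibitors were split, with 2 of 20 higher, 4 lower and 14 not passing (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0967). Cdkn1a, p21, rose 3.48-fold and Wee1, a kinase that restrains Cdk1, rose 5.71-fold, whereas the growth arrest gene Gas1 fell by 1.25 on the log2 scale, Tob2 by 1.13, Cdkn1c by 1.58 and Rbl2 by 0.47. Of 21 p53 targets 4 rose, 1 fell and 16 did not pass (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.398). Those that rose were Phlda3 at 1.89, Cdkn1a, Ckap2 and Perp at 0.97, and the member that fell was listed as 9030617O03Rik, and with library totals alone 9 were higher and 0 lower.

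Ribosome biogenesis genes and MYC targets rose as a list, with 37 of 59 members higher, 3 lower and 19 not passing (40 higher and 3 lower adjusted over the list alone; median 0.75; camera adjusted p = 8.98e-10; adjusted p = 0.202 with an estimated correlation). Nucleophosmin (Npm1) rose, nucleostemin (Gnl3) rose by 1.42 on the log2 scale and the RNA polymerase I subunit gene Polr1e by 1.53. The members that fell were Fkbp4 at -1.61, Lyar at -0.53 and Eif4e at -0.49. The medians of matrix genes (1.21) and fibroblast markers (0.65) were higher in the same libraries. Pluripotency network genes other than the delivered factors were scarcely measured, since 4 of 31 were in the table and 2 were tested, Esrrb (log2 fold change 0.12, limma adjusted p = 0.629) and Rif1 (0.04, adjusted p = 0.848). Esrrb passed with library totals alone (0.48, adjusted p = 0.0449). Nanog, Lin28a and Runx1 were not in the table and were not analysed here. Chromatin and DNA methylation enzymes had 2 of 30 members higher, 5 lower and 23 not passing (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.922), with a median of 0.03 and a mean of -0.02, so that median and mean differed in sign. With library totals alone the chromatin list had 11 members higher and 0 lower and a median of 0.39.

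**Figure D3:**
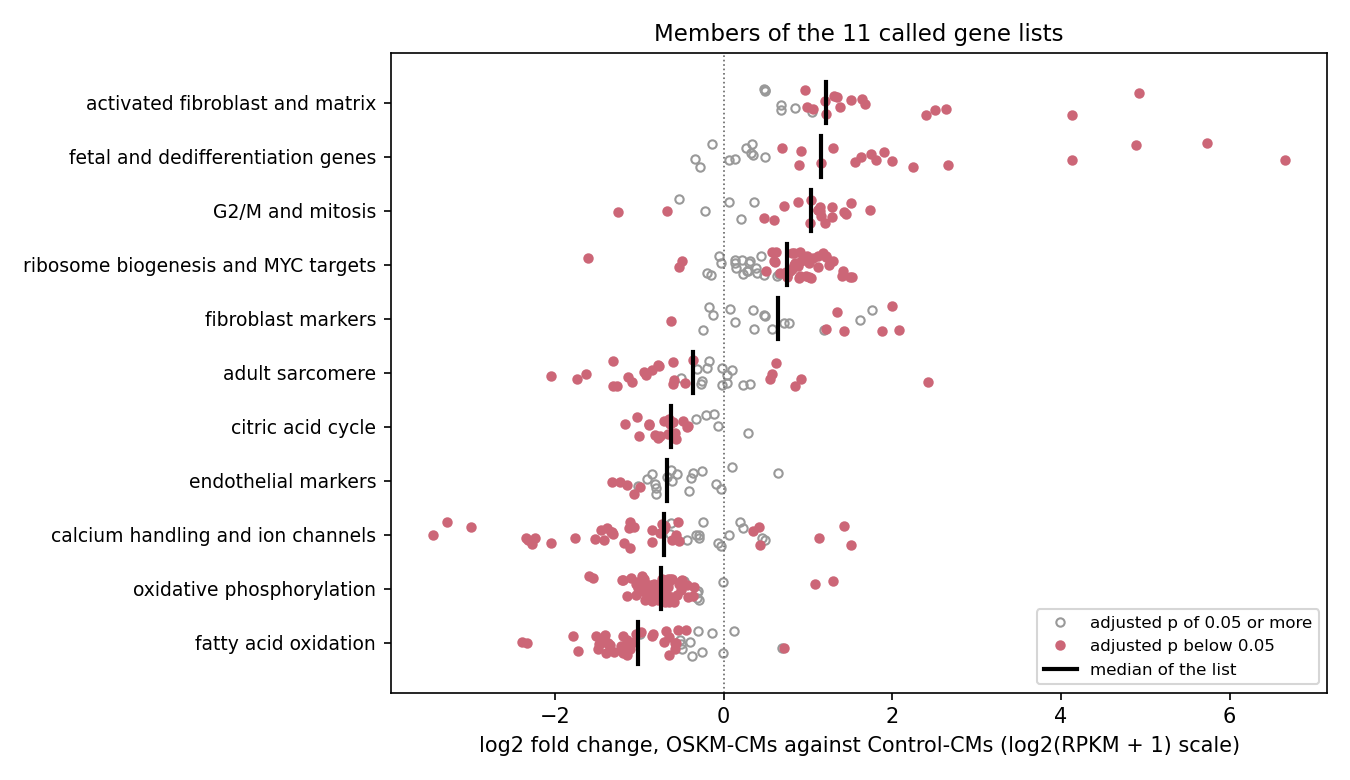
Log2 fold changes, OSKM-CMs (n = 3) minus Control-CMs (n = 2), of the members of the 11 lists with a camera adjusted p below 0.05; filled points passed limma at an adjusted p below 0.05, open points did not, and the black line is the list's median. Medians run from 1.21 for activated fibroblast and matrix genes to -1.02 for fatty acid oxidation, and none of these 11 medians changed sign between the scalings tried.

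Stress and signalling lists were not called by camera, although single members changed, and fry called the integrated stress response (adjusted p = 0.000745), cytokine (0.0126) and autophagy (0.0334) lists as higher. In the integrated and mitochondrial stress response list, 10 of 26 members rose, 2 fell and 14 did not pass (10 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.126). Genes of serine, folate and amino acid supply were among those that rose, with log2 fold changes of 2.33 for Asns, 1.90 for Mthfd2, 1.51 for Psat1 and 1.79 for Aldh18a1, and the transcription factor Atf4 rose by 0.68. Vldlr and Cebpb fell by 1.51 and 1.35. The unfolded protein response list had 1 of 25 members higher, Ero1l, 3 lower and 21 not passing (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.416). Those 3 were Dnajb9, Hyou1 and Hspa5, and with library totals alone the list had 7 members higher and 0 lower. Dnajb9 did not pass with library totals alone (adjusted p = 0.0749), and Hspa5 passed neither with them (adjusted p = 0.526) nor without OSKM-CMs replicate 1 (0.0566), OSKM-CMs replicate 3 (0.0578), Control-CMs replicate 3 (0.0616) or Control-CMs replicate 5 (0.055). No member of the interferon response list passed among 37 tested (0 higher and 0 lower adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.0535). In limma 2 of the 37 had an unadjusted p below 0.05, and limma voom called 2. For this interferon list, no filter and the 2-library filter, which kept the same genes, are counted below as separate settings. That list's camera adjusted p was below 0.05 in 7 of 19 other settings and ran from 3.61e-06 without Control-CMs replicate 5 to 0.817 without Control-CMs replicate 3, and it was 0.000358 without OSKM-CMs replicate 3.

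Of 8 cytokine and chemokine genes tested, 4 rose, 1 fell and 3 did not pass (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0932). Il33, an alarmin, rose by 2.50 on the log2 scale (12.4-fold by group means), Tgfb3 by 1.05 (2.57-fold) and Cx3cl1 by 1.04 (2.87-fold). Csf1 rose by 0.58, and Tgfb1 fell by 0.65. Immediate early genes had 3 of 22 higher, 4 lower and 15 not passing (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.301). Those higher were Maff, Fosl2 and Hspa8, and those lower were Egr1, Fos, Klf2 and Arc. Fos did not pass without Control-CMs replicate 5 (adjusted p = 0.0647), and Hspa8 did not pass without it (0.0818) or without OSKM-CMs replicate 3 (0.0574). Epithelial genes had 2 of 5 higher, Marveld2 and Perp, and 0 lower (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0875). In the mesenchymal transition list 4 of 13 rose, 2 fell and 7 did not pass (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0875). Those higher were Cd44 at 2.92 (14.8-fold by group means), Vim at 1.55 (3.03-fold), Fn1 at 1.20 (4.55-fold) and Tgfbi at 0.88. Prrx1 at -1.08 was among those lower. Without OSKM-CMs replicate 2 the epithelial and mesenchymal lists each had a camera adjusted p of 0.0242. YAP/TEAD targets had 5 of 17 higher, 2 lower and 10 not passing (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.483), with a median of -0.02 and a mean of 0.35 that differed in sign. Among them Nt5e rose by 2.59, Ctgf by 2.24, Ankrd1 by 2.00, Crim1 by 1.27 and F3 by 0.50, and Gadd45a and Amotl1 fell. Autophagy and lysosome genes had 8 of 30 higher, 2 lower and 20 not passing (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.117), with cathepsin B (Ctsb) at 1.73 and Atg13 at 1.14 among those higher and Map1lc3a at -0.81 and Wipi1 at -0.59 lower. With library totals alone that list had 18 members higher, 1 lower, a median of 0.55 and a camera adjusted p of 0.048. Medians of the cardiac transcription factor, cell cycle inhibitor, unfolded protein response, immediate early, YAP/TEAD, mural cell and macrophage lists changed sign with library totals alone, which moved the median of all genes to 0.36.

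Markers of other heart cell types moved in different directions. Activated fibroblast and matrix genes rose, with 16 of 23 higher, 0 lower and 7 not passing (19 higher and 0 lower adjusted over the list alone; median 1.21; camera adjusted p = 7.10e-08; adjusted p = 0.47 with an estimated correlation). Postn (ENSMUSG00000027750.9), periostin, rose 32.9-fold. Elastin (Eln) rose by 2.50 on the log2 scale (8.90-fold by group means) and Col8a1 by 2.63 (11.3-fold). In the fibroblast marker list 6 of 22 rose, 1 fell and 15 did not pass (7 higher and 1 lower adjusted over the list alone; median 0.65; camera adjusted p = 0.00885; adjusted p = 0.58 with an estimated correlation). Those that rose were Col3a1 at 2.00, Col1a2 at 2.08, Col1a1 at 1.87, Serpinf1 at 1.43, Col6a1 at 1.35 and Lox at 1.22. Their folds of mean scaled RPKM, in the same order, were 4.53, 6.79, 7.03, 3.87, 3.15 and 7.39. The member that fell was Fbln1 at -0.62. The camera call on this list ended with library totals alone (adjusted p = 0.132), without OSKM-CMs replicate 1 (0.0509) and without Control-CMs replicate 5 (0.312), and fry did not call it (adjusted p = 0.274). With limma voom, Postn, Col1a1 and Col1a2 did not pass (adjusted p = 0.0587, 0.0643 and 0.0796), at log2 fold changes of 4.89, 2.72 and 2.67.

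Endothelial markers were lower, with 5 of 23 members lower, 0 higher and 18 not passing (0 higher and 3 lower adjusted over the list alone; median -0.67; camera adjusted p = 0.00156; adjusted p = 0.58 with an estimated correlation). The members that fell were Kdr, a receptor of vascular endothelial growth factor, at -1.32, Cd300lg at -1.23, Fabp4 at -1.14, Gpihbp1 at -1.06 and Egfl7 at -0.99. With library totals alone 2 members were lower and the median was -0.30, and fry did not call the list (adjusted p = 0.285). Egfl7 did not pass with library totals alone (adjusted p = 0.0547) or without Control-CMs replicate 3 (0.0614), and Cd300lg did not pass without OSKM-CMs replicate 3 (0.0544), Control-CMs replicate 3 (0.0636) or Control-CMs replicate 5 (0.0954). Mural cell markers had 2 of 15 higher, Cspg4 at 3.07 and Pdgfrb at 0.89, and 2 lower, Pln and Itga7, which cardiomyocytes also express (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.428). Macrophage and monocyte markers had 1 of 14 higher, Lgals3 at 1.21, and 0 lower (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.605, and 0.0194 without Control-CMs replicate 5). All 3 Schwann and neural markers tested were higher, with S100b at least 29.2-fold higher against the pooled floor, Cnp at 1.02 and Prnp at 0.50. Prnp did not pass without OSKM-CMs replicate 1 (adjusted p = 0.0652), OSKM-CMs replicate 3 (0.0707), Control-CMs replicate 3 (0.0879) or Control-CMs replicate 5 (0.088). None of 5 mesothelial markers passed limma, where 2 had an unadjusted p below 0.05, and limma voom called 1 (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0971), among them C3 (log2 fold change -1.01, adjusted p = 0.0566), Upk3b (adjusted p = 0.0758) and Gpm6a (-0.74, adjusted p = 0.136). Without Control-CMs replicate 3, Upk3b and Gpm6a passed (adjusted p = 0.0124 and 0.0124), and C3 passed without OSKM-CMs replicate 1 (0.0426) or OSKM-CMs replicate 2 (0.0363). The list's camera adjusted p was 0.0125 without Control-CMs replicate 3, 0.0495 without OSKM-CMs replicate 3 and 0.0143 with library totals alone. The red cell and platelet list had 1 tested gene, the globin Hbb-b1, which was lower (log2 fold change -1.76, adjusted p = 0.0317) and did not pass without OSKM-CMs replicate 1 (0.0657), Control-CMs replicate 3 (0.137) or Control-CMs replicate 5 (0.0715). No lymphocyte or neutrophil marker was tested.

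The deposited table carried the authors' own likelihood-ratio test of the same groups, with 2039 genes higher and 1916 lower in OSKM-CMs at a false discovery rate below 0.05. Among the 10915 genes tested here, the authors' table called 3602 and limma called 3298. The calls shared 3075 genes, and all 3075 had the same sign in both. The log2 fold changes of the 2 sources had a Pearson r of 0.94 across genes, which are not independent replicates.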

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

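The pseudocounts of 0.1 and 5 were chosen after the data were seen, and the other settings were planned. A DESeq2 test, planned as an alternative, was not run. No named gene that was called, in the main fit or in the alternative, reversed its direction. Of 1733 values for 116 named genes over 15 settings, 1666 kept their side of the threshold, 47 lost the call and 20 gained it. The 1666 may include uncalled genes whose direction changed, since such changes were counted as kept. Library totals alone gave 3985 genes higher and 650 lower, in step with a median of all genes moved to 0.36, and kept 2390 of the 3298 calls. Leaving out each library in turn gave 1158 to 1563 genes higher, 953 to 1504 lower, 2215 to 3067 changed and 1056 to 1304 changed at least 2-fold, and 2029 to 2759 of the calls were kept with fewer samples to test. Leaving out a control left 1 control library, which was assumed to vary like OSKM-CMs. With a pseudocount of 5, 528 genes changed at least 2-fold, since a larger added value shrinks folds. Of the 11 lists called, 0 were called with an estimated correlation (adjusted p from 0.202 to 0.58), and fry called 24 of 29 in its mixed form and 14 in its directional form, which ask other questions. Camera with an estimated correlation rests on 3 degrees of freedom. These losses therefore cannot separate correlation between genes from the small number of libraries. All 4 factors were called in every setting. Depth limits what can be said of mitotic genes, since Cdk1 and Ccna2 had 3 control reads each.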

Other observations

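The gene groups in this part were chosen after the data were seen, as were the paralogue pairs and all tests below except those on gene length and GC content. Genes of the cytosolic translation machinery were higher, in the same libraries in which matrix genes (median 1.21) and fibroblast markers (median 0.65) were higher. Of 80 cytosolic ribosomal protein genes tested, 60 rose and 0 fell, with a median log2 fold change of 0.52 (camera adjusted p = 4.94e-15 over 12 groups; adjusted p = 0.353 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases had 13 of 20 higher and 0 lower (median 0.57; adjusted p = 9.67e-06; adjusted p = 0.273 with an estimated correlation), and 7 of 8 subunits of the cytosolic chaperonin rose (median 0.73; adjusted p = 7.72e-05; adjusted p = 0.273 with an estimated correlation). Among 61 small nucleolar RNAs 19 rose and 0 fell (median 0.66; adjusted p = 1.74e-05; adjusted p = 0.353 with an estimated correlation). Mitochondrial ribosomal protein genes went the other way with 21 of 75 lower and 2 higher, but their median of -0.15 became 0.26 with library totals alone. Proteasome subunits were not called as a group (3 higher, 1 lower of 36; adjusted p = 0.154). Tubulins had 7 of 13 higher and 2 lower, S100 calcium-binding proteins 5 of 7 higher and annexins 4 of 8 higher, with adjusted p = 0.0139, 0.000553 and 0.00347, or adjusted p = 0.405, 0.193 and 0.353 with an estimated correlation. Potassium channel genes fell in 13 of 21 cases and rose in 2 (median -0.87; adjusted p = 2.37e-06; adjusted p = 0.193 with an estimated correlation), and glutathione transferases fell in 7 of 14 and rose in 1 (median -0.62; adjusted p = 0.00317; adjusted p = 0.193 with an estimated correlation). The medians of these groups, apart from the mitochondrial ribosomal proteins, kept their sign under every scaling tried.

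Interferon response genes separated libraries within each group. The list's median, relative to the mean of the libraries, was 0.83 in Control-CMs replicate 3 and -0.30 in Control-CMs replicate 5, and 0.52 in OSKM-CMs replicate 3 against -0.30 and -0.64 in OSKM-CMs replicates 1 and 2. Gbp2, a guanylate-binding protein, was at 26.4 scaled RPKM in Control-CMs replicate 3 and 4.92 in replicate 5, and at 12.9 in OSKM-CMs replicate 3 against 3.37 and 1.54 in replicates 1 and 2. Cd74, a gene of antigen-presenting cells, went with the same libraries, at 24.3 and 4.63 in Control-CMs replicates 3 and 5 and at 18.9 in OSKM-CMs replicate 3 against 6.03 and 1.83 in replicates 1 and 2, and so did H2-Aa.

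In the matrix list 16 of 23 genes rose and in the fibroblast list 6 of 22, while 5 of 23 endothelial markers fell (2 with library totals alone), and the camera calls were lost at adjusted p = 0.47, 0.58 and 0.58 with an estimated correlation. The fibroblast median exceeded the endothelial median by 1.32 (95% bootstrap interval 0.89 to 2.06), which argues against a larger share of all non-myocyte cells as the whole cause. This difference restates the pattern, which was seen before the test was chosen, so its interval is no separate evidence. Bootstrap intervals here and below resampled genes and not libraries, so they leave out the spread between libraries. Mural and macrophage medians were both -0.20 (-0.58 to 0.17 and -0.65 to -0.00057), but were 0.15 and 0.08 with library totals alone. The mural list also holds Pln and Itga7, which cardiomyocytes express, so these medians cannot carry the argument. A trend on gene length and GC content common to all genes is argued against as well: it held 0.554% of the variance with fitted values from -0.28 to 0.20, while the matrix minus endothelial difference was 1.88 before and 1.92 (1.57 to 2.30) after its removal. A larger share of fibroblasts, or of activated ones, stays open: the matrix median exceeded that of fibroblast markers outside the matrix list by 0.56, with an interval of -0.18 to 1.03 that includes 0, although the abundant fibroblast transcripts Dcn (31.4 to 52.8 scaled RPKM) and Dpt (6.32 to 6.23) did not pass the test, nor did Gsn. Those fibroblast markers include the collagen genes Col1a1, Col1a2, Col3a1 and Col6a1 and also Lox, so the comparison cannot separate fibroblast share from matrix expression. Matrix expression by the cardiomyocytes themselves may also contribute and was not tested.

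In pairs of related genes, listed after the pattern was seen and so no independent evidence of it, the broadly expressed member was called higher relative to the muscle-type member in 20 of 24 pairs and called lower in 1, with 10 pairs in which the broad member rose and the muscle-type member fell. Examples were Rpl3 against Rpl3l (difference 5.70 on the log2 scale), Eef1a1 against Eef1a2 (4.37) and Slc25a5 against Slc25a4 (2.61), and the pair called lower was Cav1 against Cav3 (-1.16). Gain and loss were within 2-fold in 4 of the 17 pairs that moved in opposite directions. This cannot settle whether reads were shared within pairs, because RPKM, which divide by gene length, were compared and not reads. Partial sharing could also escape it, and how shared reads were assigned is not stated. The same trend on length and GC content, whose fitted values span -0.28 to 0.20, is argued against (median difference 1.92 before its removal and 1.95, lower bound 1.20, after). A larger share of all non-myocyte cells is argued against too, since endothelial markers did not rise with the broad members, which exceeded them by 1.79 (1.08 to 2.24). These are the same endothelial markers, seen to be lower before the test was chosen. A larger share of fibroblasts stays open, since the broad members exceeded fibroblast markers by 0.071 (-1.10 to 0.78), beside the hypothesis that cardiomyocytes with the factors may have exchanged muscle-type for broadly expressed forms.

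All 13 mitochondrially encoded genes tested fell, with a median of -1.49, including mt-Co1 (-1.54) and mt-Nd1 (-1.91). The trend on length and GC content, with a lowest fitted value of -0.28, is argued against, since the median was -1.57 (-1.61 to -1.23) after its removal. A loss of mitochondrial RNA, for example during isolation, stays open, since the difference from nuclear oxidative phosphorylation genes was -0.74 (-0.89 to -0.46). A lower mitochondrial content of OSKM-CMs may account for the same difference and was not tested apart from it.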
